A study of Mus musculus with 12 samples.

How the data were processed

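RNA of purified bone-marrow pro-B cells, as the tissue label has it for all arrays, was measured on 12 Affymetrix Mouse Gene ST arrays, 4 each of WT, Pax5+/- and Cd72+/-;Pax5+/-. Per the labels, RNA was extracted with TRIzol and purified on columns with DNase treatment, and the targets were fragmented and labelled with biotin, and the authors analysed the arrays with the Transcriptome Analysis Console. The table deposited by the authors holds log2 signal values for each transcript cluster, and the range of 3.67 to 14.73 and array medians of 6.91 to 7.005 were checked against that unit. Background correction, normalization, probe summarization and genome build are not given in the sources used here, so no coordinates are printed. Groups were taken from the sample titles. The titles number the samples from 1 to 12 and share no number between groups, so the groups could not be paired. The labels do not say whether the arrays of a group came from separate animals or repeat 1 sample. The number of arrays limits the precision.

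Of 28944 clusters, 21789 carry 1 gene symbol, 1621 carry several and 5534 carry none. The 23410 with a symbol were tested, with no filter on signal and no second normalization. Clusters with 1 symbol name 19938 genes, 999 of them through more than 1 cluster, and such a gene is represented by the cluster with the highest mean. For genes on chromosome X or Y and for the order of neighbours, 19856 genes were matched by Entrez identifier to the RefSeq table of assembly GRCm38.p6, from which only names, chromosomes and order were used.

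A linear model with a mean per group was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a constant prior; 9 residual and 3.28 prior degrees of freedom), and 3 contrasts were tested: Pax5+/- against WT, Cd72+/-;Pax5+/- against WT, and Cd72+/-;Pax5+/- against Pax5+/-. A cluster was called at a Benjamini-Hochberg adjusted p under 0.05. The study states a threshold of p under 0.05 with a change over 2-fold, without saying whether that p is adjusted. That threshold was counted with an unadjusted p, and the clusters that also passed after adjustment were counted too. Standard errors are those of the contrast after moderation of the variance by the prior, and SDs are over the 4 arrays of a group. Exact two-sided permutation tests of single genes, 4 arrays against 4, cannot give a p below 0.0286. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

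The 32 gene lists were written from general knowledge and tested with limma's camera (two-sided, preset correlation 0.01, adjusted over the lists) and again with a correlation estimated per list. The fry test was run as an alternative. Its directional p asks whether a list's genes move one way on balance, and its mixed p whether they change in either direction, and neither compares the list with other genes. Past the directional test were 6, 9 and 5 lists, and past the mixed test 24, 20 and 25, in the order of the contrasts above. Each list's count is also given adjusted over the list alone. Genes were named by a rule: Pax5 and Cd72 always; in each contrast up to 8 of the largest rises and 8 of the largest falls among called clusters with 1 symbol and no overlap between the groups; and in each list up to 4 called members with the smallest adjusted p, with up to 2 members that did not pass given by value only. Names outside the rule were chosen after their values were seen. Groups, contrasts, threshold, lists, the naming rule and the first set of alternatives were chosen before the data were examined.

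The first set of alternatives was quantile normalization, arrays shifted to a common median, a filter on dim clusters, all clusters with or without symbols, a prior with trend and robust fit, only the compared groups in the fit, array weights, an adjusted p under 0.1, omission of each array in turn, the fry test and the estimated correlation, WT arrays divided between the comparisons, only the mutant groups for their difference, and the mean of a gene's clusters. Others were added after the arrays were seen: the closest pair of arrays averaged or treated as a random block, the mean of the stromal markers as a covariate, omission of replicates 1 and 3 of WT and Pax5+/-, omission of genes on chromosomes X and Y, and lists without certain members. A comparison of the WT and Pax5+/- arrays of 1 closest pair with those of the other was computed and set aside, because those pairs were chosen from the same values.

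Shared WT arrays alone make the changes of both mutants correlate, so their overlap was set beside 100 simulations of unchanged groups and beside comparisons with WT arrays divided between them. The pipeline was tested on simulated data for each contrast, with 200 of 23410 clusters changed. Of changes of 1.41-fold, 68.2%, 78.8% and 78.8% were recovered in the order of the contrasts above, of 2-fold changes 100%, 94% and 97%, and of 4-fold changes 100% in each. Of the calls 4.79%, 5.7% and 6.12% were false. The simulated arrays were drawn independently, without closest pairs, so these rates do not cover real arrays that repeat 1 sample. No column of values was left unused, and the clusters without a symbol were used only in an alternative and in the closing section.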

Results

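Gene expression was measured in pro-B cells, the bone-marrow precursors in which the antibody genes are assembled, from mice 1 month old kept free of specific pathogens. The 12 arrays formed 3 groups of 4: wild type (WT), mice that carry a single working copy of Pax5 (Pax5+/-), and mice that lack 1 copy each of Pax5 and Cd72 (Cd72+/-;Pax5+/-). Pax5 encodes the transcription factor that holds cells in the B lineage, and Cd72 encodes an inhibitory co-receptor of B cells. All arrays carry the same tissue label, while the sample titles and cell-type labels call the WT cells pro-B cells and those of both mutant groups preleukemic precursor B cells, and the series title ties loss of both genes to B-cell leukemia. The comparisons therefore ask what loss of 1 copy of Pax5 changed, and what the added loss of 1 copy of Cd72 changed. Of 28944 transcript clusters on the arrays, the 23410 paired with a gene symbol were tested with limma on the deposited log2 values. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate animals, so the p-values measure only the spread between these arrays, which may be technical.

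Array medians lay between 6.91 and 7.005 on the log2 scale. The first principal component held 37.2% of the variance and ran from the Pax5+/- arrays (-18.9 to -22.2) to the Cd72+/-;Pax5+/- arrays (18.6 to 21.4). The WT arrays were divided on it, with replicates 1 and 3 at -10.7 and replicates 2 and 4 at 12.2 and 11.3. Within the WT group, replicates 1 and 3 and replicates 2 and 4 differed from each other with an SD of 0.109 to 0.117 and no cluster by over 2-fold, while the other WT pairs differed with an SD of 0.27 to 0.28 and by over 2-fold in 199 to 225 clusters. The Pax5+/- arrays paired in the same way, with SDs of 0.122 to 0.177 inside the closest pairs and 0.195 to 0.281 outside them. In Cd72+/-;Pax5+/- the closest pairs gave 0.117 to 0.125 and the others 0.128 to 0.183. The labels neither state nor exclude that the closest pairs are repeat arrays of 1 sample, so each count is given with every array as a replicate and again with the closest pairs averaged, a setting chosen after the arrays were seen. The mean of the stromal and endothelial markers also divided the arrays, through stromal genes such as Col1a1, Col1a2, Sparc and Cxcl12. The endothelial markers Kdr, Emcn and Cdh5 were flat. The endothelial marker Pecam1 divided the WT arrays in the same way, at 10.44, 9.24, 10.35 and 9.25 in WT replicates 1 to 4. In Pax5+/- replicates 1 to 4 it was at 10.24, 10.54, 10.31 and 10.56. These genes were singled out after their values were seen. The mean was 7.54 and 7.53 in WT replicates 1 and 3, 7.18 and 7.21 in WT replicates 2 and 4, 7.30 and 7.36 in Pax5+/- replicates 1 and 3, 6.81 and 6.84 in Pax5+/- replicates 2 and 4, and 6.69 to 6.79 in the 4 Cd72+/-;Pax5+/- arrays.

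**Figure D1:**
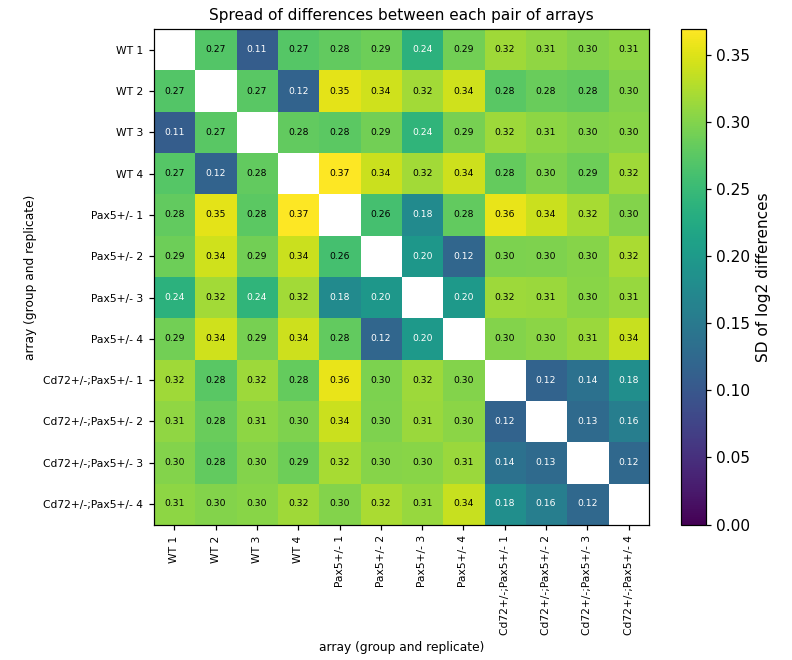
Each cell gives the SD of the log2 differences between 2 arrays over the 23410 tested clusters, with the 12 arrays along both axes and colour running from 0 (dark) to the highest value (yellow). The closest WT pairs lie at 0.109 to 0.117, against 0.27 to 0.28 for the other WT pairs and 0.237 to 0.369 between groups.

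Pax5 (transcript cluster 10512669) had a signal of 11.57 ± 0.148 in WT, 10.97 ± 0.26 in Pax5+/- and 11.2 ± 0.0835 in Cd72+/-;Pax5+/- (log2, SD, n = 4). It fell by 0.60 in Pax5+/- against WT (SE 0.114, limma adjusted p = 0.0051, 1.51-fold lower). The change of -0.36 in Cd72+/-;Pax5+/- against WT did not pass (adjusted p = 0.0781), although the 4 arrays of each group did not overlap (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). Cd72 (transcript cluster 10512470) had a signal of 8.90 ± 0.51 in WT, 10.19 ± 0.111 in Pax5+/- and 7.51 ± 0.135 in Cd72+/-;Pax5+/-. It fell by 1.39 in Cd72+/-;Pax5+/- against WT (adjusted p = 0.000492) and changed by -2.67 against Pax5+/- (adjusted p = 1.41e-06, 6.39-fold lower), and it rose by 1.29 in Pax5+/- against WT (adjusted p = 0.000827). Each of these Cd72 comparisons had an exact permutation p of 0.0286. WT replicates 1 and 3 read 9.29 and 9.39 for Cd72, and replicates 2 and 4 read 8.49 and 8.43. With the closest pairs averaged, the fall of Cd72 against Pax5+/- kept its call, and the calls of Pax5 in Pax5+/- and of Cd72 in both comparisons with WT ended. The parts of both genes that were deleted, and whether the probes lie inside them, are not given in the sources used here, so these levels check the labels only in part.

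Sex-linked transcripts separated the groups completely. Xist, the RNA that silences an X chromosome in female cells, read 11.75 to 11.9 on the Cd72+/-;Pax5+/- arrays and 5.00 to 5.52 on the WT and Pax5+/- arrays. The Y-linked gene Uty read 4.88 to 5.19 on the Cd72+/-;Pax5+/- arrays and 8.85 to 9.74 on the others. Every comparison with Cd72+/-;Pax5+/- is therefore also a comparison of arrays with Xist signal against arrays with Uty signal, and the genotype cannot be told apart from it.

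**Figure D2:**
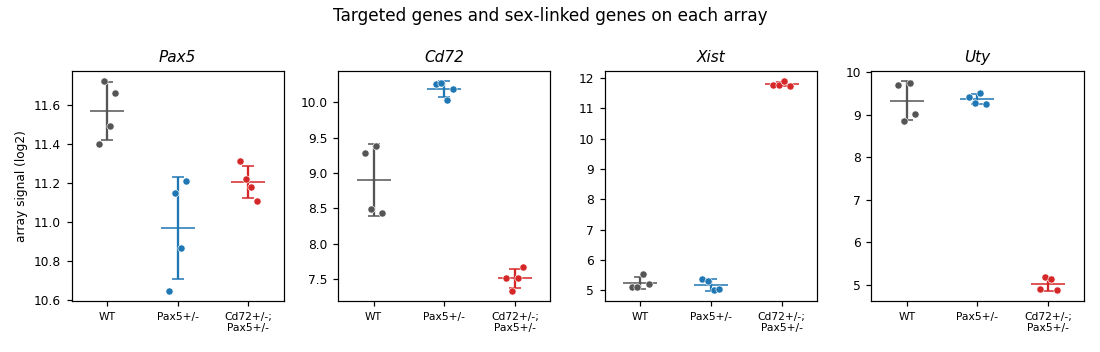
Log2 array signal (vertical axes, each with its own range) of Pax5, Cd72, Xist and Uty in WT, Pax5+/- and Cd72+/-;Pax5+/-, with 1 point per array, a bar at the mean and error bars of 1 SD (n = 4). Cd72 was lowest in Cd72+/-;Pax5+/- (7.51 ± 0.135), and Xist was high on those 4 arrays (11.75 to 11.9).

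Single genes changed more than 10-fold in cells that lacked 1 copy of Pax5 alone. Pgr, the progesterone receptor, rose 11.4-fold to 9.505 ± 0.199 from 5.995 ± 0.119 in WT (log2, SD, n = 4; log2 change 3.51, SE 0.0944, limma adjusted p = 3.14e-10). Il18r1, a subunit of the interleukin-18 receptor, rose 9.92-fold (SE 0.173 on the log2 scale, adjusted p = 8.39e-08), and the chemokine Ccl3 rose 7.1-fold (SE 0.191, adjusted p = 9.19e-07). Alpl, the tissue-nonspecific alkaline phosphatase, fell by 3.77 on the log2 scale, to 7.32 ± 0.0479 from 11.09 ± 0.336 (SE 0.133, adjusted p = 3.03e-09), and Rnase12, of the ribonuclease A family, fell by 3.73 (SE 0.0727, adjusted p = 2.39e-11). The other largest rises were Trav14-1, a T-cell receptor alpha variable segment, the mitochondrial membrane protein gene Fundc2, the tetraspanin Tspan2, Frmd4b and Mrgpra1, at 3.48, 3.35, 3.32, 3.08 and 2.91. The other largest falls were Mt2, a metallothionein, Atp1b1, a sodium pump subunit, Tjp1, a tight-junction scaffold, the Slam-family receptor Cd84, Eng, a co-receptor for TGF-beta, and the cholesterol exporter Abca1, between -3.06 and -2.28.

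In all, 1749 of 23410 clusters passed in Pax5+/- against WT, 1001 higher and 748 lower, with a median absolute log2 change of 0.455. The study's threshold, counted here with an unadjusted p under 0.05 and a change over 2-fold, was met by 224 clusters, 144 higher and 80 lower. Of these, 220 also passed after adjustment. Among all clusters 10.7% had no overlap between the groups, against 2.86% by chance if the 8 arrays are independent. If the closest pairs repeat 1 sample, 2 units per group give up to 33.3% by chance, more than the shares observed in any of the 3 comparisons. With the closest pairs averaged, 282 of the 1749 passed, among them 135 of the 220 with a change over 2-fold and all of the 8 largest rises and 8 largest falls except Abca1. Without replicates 1 and 3 of WT and Pax5+/-, left out after their higher stromal markers were seen, 5359 clusters passed. That setting leaves 1 closest pair in each of these groups, so its small spread adds and keeps calls by construction, and its counts are no check on stromal content. With the mean of the stromal markers as a covariate, also chosen after the arrays were seen, 1425 of the 1749 kept their call. That mean includes Alpl, itself among the largest falls in Pax5+/-. The covariate thus carries part of the group difference, and its counts are no check on stromal content either.

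Among the gene lists fixed before the data were examined, 4 of 32 passed in this comparison with limma's camera test at a preset correlation of 0.01, and none with a correlation estimated per list. Members named beyond the 4 with the smallest p in a list were chosen after their values were seen. Immediate-early genes are induced by acute stimulation and cell handling. Of 14 members, 5 rose (Nr4a1, Zfp36, Jun, Fosb and Fos), 7 adjusted over the list alone, none fell and 9 did not pass (adjusted p = 0.000407, and adjusted p = 0.24 with an estimated correlation). Nr4a1, an orphan nuclear receptor induced by antigen-receptor signals, rose by 1.06 (SE 0.0857). Of 21 S-phase and replication genes 5 fell, 8 adjusted over the list alone, and none rose (adjusted p = 0.000407, and adjusted p = 0.863 with an estimated correlation). They were Rrm2, a subunit of ribonucleotide reductase, at -0.91 (SE 0.0837), Ccne1 at -0.43, Uhrf1 at -0.27, Mcm4 at -0.22, and Cdc6. Of 19 G2 and M phase genes 2 fell, Top2a at -0.28 and Bub1b at -0.23, and 3 fell adjusted over the list alone (adjusted p = 0.0085, and adjusted p = 0.863 with an estimated correlation). Of 13 glycolysis genes 2 fell, the phosphofructokinase Pfkp at -0.59 and the glucose transporter Slc2a1 at -0.41, and 3 fell adjusted over the list alone (adjusted p = 0.0201, and adjusted p = 0.907 with an estimated correlation). The glycolysis call also ended with the closest pairs averaged (adjusted p = 0.0555), with the filter on dim clusters (adjusted p = 0.0626), with fry (adjusted p = 0.278) and without replicate 2 or 4 of either group (adjusted p = 0.0854 to 0.241). The G2 and M phase call ended after quantile normalization, with fry (adjusted p = 0.0589), without replicates 1 and 3 of both groups, and without Pax5+/- replicate 4 (adjusted p = 0.069). The calls of Rrm2 and Nr4a1 held with the closest pairs averaged, and those of Zfp36, Jun, Fosb, Ccne1, Uhrf1, Mcm4, Top2a, Bub1b, Pfkp and Slc2a1 ended.

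Known targets of Pax5 moved both ways in Pax5+/-. Of 21 genes that Pax5 activates, Capn2, Cd72, Ikzf3 and Irf4 rose, Bst1, Spib, Cd79a and Id3 fell, and 13 did not pass (5 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.817). Bst1, a stromal and B-cell surface enzyme, fell by 2.01 (SE 0.195), and Spib, a transcription factor of B cells and plasmacytoid dendritic cells, fell by 1.27 (SE 0.156). Of 14 genes that Pax5 represses, Ccl3, Flt3, Cd28 and Cd33 rose and Grap2 and Xbp1 fell (5 and 3 adjusted over the list alone, adjusted p = 0.267); Flt3, a receptor of early progenitors, rose by 1.07 (SE 0.099). Of 22 genes of pro-B and pre-B identity, Cd93, Ebf1 and Cd24a rose and Tcf3, Pax5 and Erg fell (7 and 4 adjusted over the list alone, adjusted p = 0.56). Of 25 genes of B-cell receptor signalling Cd22, Cd72, Lat2 and Ptpn6 rose and Cd79a, Pik3cd and the kinase Prkcb fell, Prkcb by 1.16 (5 and 5 adjusted over the list alone, adjusted p = 0.41). Of 21 genes of immature and mature B cells, Cd22 rose and Ccr7, Cxcr5 and Ltb fell (1 and 3 adjusted over the list alone, adjusted p = 0.267). Of 26 driver and suppressor genes of B-cell acute leukemia Ebf1, Flt3 and Ikzf3 rose and Bcor, Erg, Tcf3 and the cell-cycle inhibitor locus Cdkn2a fell, Cdkn2a by 0.99 (3 and 5 adjusted over the list alone, adjusted p = 0.786). Of the genes that the naming rule covers, the calls of Capn2, Prkcb, Ccl3 and Cdkn2a held with the closest pairs averaged, and those of Cd72, Irf4, Bst1, Spib, Flt3, Cd28, Grap2, Cd93, Ebf1, Tcf3, Pax5, Cd22, Ptpn6, Ccr7, Cxcr5 and Ltb ended.

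The other lists did not pass in Pax5+/- against WT. Among 22 interferon-response genes Bst2, Gbp3 and Ifih1 fell (3 adjusted over the list alone, adjusted p = 0.177). Ccnd3 fell among 18 genes of interleukin-7 and JAK-STAT signalling, Ccl3 and Nlrp3 rose among 18 of NF-kB and inflammation, and Insr rose while Slc2a1 fell among 11 of Pax5-linked glucose restriction. No member passed among 16 p53 targets, 19 oxidative phosphorylation genes, 18 Myc targets (adjusted p = 0.0686) or 9 heat-shock genes. Of 41 neighbours of Cd72 and Pax5 on their chromosome, Car9, Gba2, Hint2 and Zbtb5 rose and Sit1 fell, and of 51 small nucleolar RNAs Snora31, Snora62, Snora73a and Snora73b rose. Markers of other cell types moved singly: Itgam rose among granulocyte markers, Aqp1 and Tfrc fell among erythroid markers, Cd28 rose and Lat fell among T-cell markers, and Nkg7 rose among NK-cell markers. Of 9 plasmacytoid dendritic cell markers Ccr9, Cox6a2 and Flt3 rose and Bst2 and Spib fell, of 11 plasma cell markers Irf4 and Sdc1 rose and Derl3, Mzb1 and Xbp1 fell, and of 13 stem and progenitor markers Flt3 rose and Meis1 and Slamf1 fell. No marker of monocytes and macrophages, of megakaryocytes, or of basophils, mast cells and eosinophils passed, and Alpl was the only one of 15 stromal and endothelial markers that passed. Of the genes in these lists that the naming rule covers, Ccl3, Nlrp3, Sit1, Lat and Alpl kept their calls with the closest pairs averaged. The lists of other cell types had adjusted p from 0.386 to 0.978, and no sex-linked gene passed. The median, the mean and the test did not share a sign for p53 targets, glucose restriction, oxidative phosphorylation, granulocyte, plasma cell, megakaryocyte and basophil lists.

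**Figure D3:**
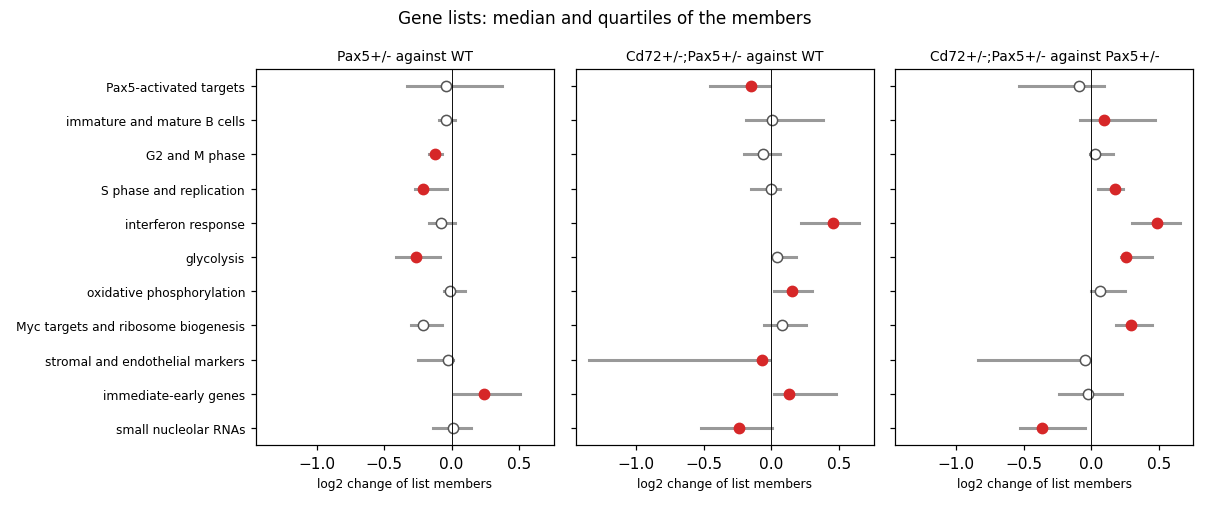
Log2 change of the members of each gene list past the camera test in 1 or more comparisons, sex-linked genes left out, in 1 panel per comparison, with a point at the median, a bar over the quartiles and a filled point where the list passed at the preset correlation. Interferon-response genes had medians of 0.454 and 0.486 in the comparisons of Cd72+/-;Pax5+/- with WT and with Pax5+/-.

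Cells that lacked 1 copy of both genes differed from WT in single genes by over 10-fold, and some of these genes are sex-linked. Slamf6, a receptor of the Slam family on lymphocytes, rose 14.5-fold to 9.70 ± 0.166 from 5.835 ± 0.257 (log2, SD, n = 4; log2 change 3.86, SE 0.114, limma adjusted p = 4.61e-10), and Slamf7 rose by 2.71 (SE 0.151, adjusted p = 1.75e-07). Ccl3 rose 9.5-fold (adjusted p = 3.18e-07), and the carbonic anhydrase Car13 rose 7.56-fold (adjusted p = 2.36e-10). Ccr2, a chemokine receptor of monocytes, fell by 3.58 (SE 0.266, adjusted p = 2.41e-06), the zinc transporter Slc30a4 fell by 3.45 (SE 0.113, adjusted p = 1.28e-09), and Rnase12 and Tjp1 fell by 3.75 and 3.68. The other largest rises, apart from Xist at 6.58, were Fundc2, the microtubule linker Hook1 and Cibar1, at 3.13, 2.75 and 2.57. The other largest falls were the Y-linked genes Uty, Eif2s3y and Kdm5d, between -4.31 and -3.40, and the zinc-finger gene Zfp709 at -3.26.

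In Cd72+/-;Pax5+/- against WT 1821 clusters passed, 965 higher and 856 lower, with a median absolute log2 change of 0.425. The study's threshold was met by 214 clusters, 93 higher and 121 lower, 197 of them also after adjustment. Among all clusters 14.8% had no overlap between the groups, against 2.86% by chance with independent arrays and up to 33.3% with the closest pairs as units. On chromosome X or Y lie 63 of the 1821. In Pax5+/- against WT, where no sex-linked gene passed, 51 of the 1749 lie there. The share of all tested clusters there is not given, and these counts do not bound the calls that follow sex. With the closest pairs averaged, 290 of the 1821 passed, among them 132 of the 197 with a change over 2-fold and all of the 8 largest rises and 8 largest falls except Zfp709. Without replicates 1 and 3 of WT and Pax5+/-, with the same limit, 4427 passed. With the stromal covariate 694 of the 1821 kept their call and 1767 kept their direction, and 1684 clusters were called in all. The covariate did not overlap between these groups (6.69 to 6.79 in Cd72+/-;Pax5+/-, 7.18 to 7.54 in WT). It therefore takes up the group difference itself, and calls lost or kept with it are no check on stromal content.

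Interferon-response genes rose in Cd72+/-;Pax5+/-. Of 22 members 12 rose, none fell and 10 did not pass, with a median log2 change of 0.454 (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.96e-11, and adjusted p = 0.259 with an estimated correlation). Rsad2, the antiviral enzyme viperin, rose by 1.55 to 7.93 ± 0.103 (SD, n = 4; SE 0.0665, adjusted p = 1.4e-08), Ifit1 rose by 1.41, Oas2 by 1.44 and the transcription factor Irf7 by 0.84. Of 14 immediate-early genes 6 rose, among them Atf3 at 0.93 and Jun at 0.77, Nr4a1 fell by 0.90 and 7 did not pass (6 and 1 adjusted over the list alone, adjusted p = 0.00233, and adjusted p = 0.259 with an estimated correlation). Of 19 oxidative phosphorylation genes Sdhc, a succinate dehydrogenase subunit, rose by 0.52 (2 higher adjusted over the list alone, adjusted p = 0.0384, and adjusted p = 0.923 with an estimated correlation). On the same arrays Xist was at 11.75 to 11.9, and 3 of the 15 stromal and endothelial markers were called lower. With the closest pairs averaged, the calls of Oas2, Irf7, Jun, Nr4a1 and Sdhc ended. The call of the oxidative phosphorylation list ended with the filter on dim clusters (adjusted p = 0.13), with fry (adjusted p = 0.442), without replicates 1 and 3 of WT and Pax5+/-, and without any 1 of WT replicates 1 and 3 and Cd72+/-;Pax5+/- replicates 3 and 4 (adjusted p = 0.0578 to 0.335).

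The lists that fell were small nucleolar RNAs, stromal and endothelial markers, genes that Pax5 activates, and sex-linked genes. Of 51 small nucleolar RNAs, which guide modification of ribosomal RNA, 16 fell and none rose, with a median of -0.242 (22 lower adjusted over the list alone, adjusted p = 1.77e-07, and adjusted p = 0.786 with an estimated correlation). Snord49a fell by 0.96, Snord49b by 0.79 and Snord42a by 0.74. Of 15 stromal and endothelial markers Alpl, Cxcl12 and Sparc fell by 2.25, 1.92 and 1.97 (5 adjusted over the list alone, adjusted p = 0.00457, and adjusted p = 0.492 with an estimated correlation). Of 21 genes that Pax5 activates 6 fell and Irf4 rose (7 and 1 adjusted over the list alone, adjusted p = 0.00391, and adjusted p = 0.923 with an estimated correlation). The lymphoid transcription factor Ikzf3 fell by 1.14 (SE 0.0853), Irf8 by 0.61 (SE 0.0801) and Cd72 by 1.39. Cd72 lacks 1 copy in this group by design, so its fall says nothing about Pax5 targets. Leaving it out gave a list median of -0.129, against -0.15 with all members, and the test was not repeated. Without replicates 1 and 3 of WT and Pax5+/- that list's median turned to 0.0325 and its call ended, and it also ended with fry (adjusted p = 0.0713) and without WT replicate 1 alone (adjusted p = 0.0613). With the closest pairs averaged, Snord49a, Alpl and Ikzf3 kept their calls, and the calls of Snord49b, Snord42a, Cxcl12, Sparc, Irf8, Irf4 and Cd72 ended. The sex-linked list had 3 members down and Xist up (the same 3 and 1 adjusted over the list alone, adjusted p = 0.000651, and adjusted p = 0.414 with an estimated correlation).

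The other lists did not pass against WT. Among 14 genes that Pax5 represses Ccl3 and Flt3 rose and Grap2 and Itgal fell (3 and 2 adjusted over the list alone, adjusted p = 0.778). Ebf1 rose and Dntt, the terminal transferase of antigen-receptor assembly, fell by 2.34 among 22 genes of pro-B and pre-B identity (2 and 2 adjusted over the list alone, adjusted p = 0.689), and WT replicates read 11.93, 9.76, 11.92 and 9.82 for Dntt. Among 25 genes of B-cell receptor signalling Cd22 and Fyn rose and Blk, Cd72 and Prkcb fell (3 and 4 adjusted over the list alone, adjusted p = 0.778). Of 21 genes of immature and mature B cells 6 rose and Cd37, Cxcr5, Il2ra and Ltb fell (7 and 6 adjusted over the list alone, adjusted p = 0.505), the rises led by Cd74, the MHC class II invariant chain, at 1.80 (SE 0.128), Ciita, the activator of MHC class II genes, at 0.69 (SE 0.0638), and H2-Aa at 0.74 (SE 0.0709). The signal of H2-Aa was low, at 5.82 in Cd72+/-;Pax5+/- and 5.075 in WT. The p53 targets Bbc3, Pmaip1, Tnfrsf10b and Zmat3 rose by 0.31 to 0.57 (4 higher and 2 lower of 16 adjusted over the list alone, adjusted p = 0.689). Of 18 genes of NF-kB and inflammation Ccl3, Ccl4 and Ptgs2 rose and Nlrp3 fell (adjusted p = 0.266), and of 21 S-phase genes Cdt1 and Chaf1b rose and Mcm4 fell. No gene of interleukin-7 signalling, of G2 and M phase or of the Myc targets passed. Pfkp rose and Pdk1 fell among glycolysis genes, Insr rose among glucose-restriction genes, and Hspa1a rose among heat-shock genes. Of 26 leukemia driver and suppressor genes Ebf1, Flt3 and Kdm5c rose and Cdkn2a and Ikzf3 fell (3 and 4 adjusted over the list alone, adjusted p = 0.778), and of 41 chromosomal neighbours Rgp1 and Zbtb5 rose and Sit1 fell. Among markers of other cells, Cd68, Aqp1, Ccl5, Cox6a2, Flt3, Irf4 and Slamf7 rose and Ccr2, Tfrc, Irf8 and Meis1 fell, no marker of granulocytes, T cells, basophils or megakaryocytes passed, and the lists had adjusted p from 0.594 to 0.958. Among the genes of these lists that the naming rule covers, Ccl3, Flt3, Cd22, Cd74, Ciita, H2-Aa, Ccl4, Nlrp3, Pmaip1, Cdkn2a, Ikzf3, Sit1, Aqp1, Ccl5, Slamf7, Ccr2 and Meis1 kept their calls with the closest pairs averaged, and the other calls ended. The median, the mean and the test differed in sign for pro-B identity, p53 targets, monocyte, plasmacytoid dendritic cell and stem cell lists.

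By the labels, Cd72+/-;Pax5+/- differs from Pax5+/- in the added loss of 1 copy of Cd72. These groups also differ completely in Xist and Uty signal, so the changes below cannot be assigned to Cd72. Slamf6 rose 17.1-fold, to 9.70 ± 0.166 from 5.6 ± 0.0529 (log2, SD, n = 4; log2 change 4.10, SE 0.114, limma adjusted p = 2.63e-10), Slamf7 rose by 2.86 (SE 0.151), and Cd48, the Slam-family ligand beside them on the chromosome, rose by 2.64 (SE 0.215). Cd44, the hyaluronan receptor, rose 7.16-fold to 8.785 ± 0.0733 (SE 0.0789 on the log2 scale, adjusted p = 2.63e-10). Tgfb3, a TGF-beta cytokine, fell by 4.17 to 6.42 ± 0.16 from 10.59 ± 0.172 (SE 0.132, adjusted p = 7.44e-10), Ccr2 fell by 3.92 (SE 0.266), and Il18r1 and Pgr, which had risen in Pax5+/- against WT, changed by -3.68 and -3.52. The other largest rises, apart from Xist at 6.62, were Car13, the mitochondrial GTPase gene Gtpbp10 and Prrg4, at 3.07, 2.75 and 2.495. The other largest falls were Uty, Eif2s3y, Kdm5d and Slc30a4, at -4.34, -4.19, -3.67 and -3.83.

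In this comparison 2292 clusters passed, 1040 higher and 1252 lower, with a median absolute log2 change of 0.432. The study's threshold was met by 280 clusters, 94 higher and 186 lower, 263 of them also after adjustment. Among all clusters 18.5% had no overlap between the groups, against 2.86% by chance with independent arrays and up to 33.3% with the closest pairs as units. On chromosome X or Y lie 80 of the 2292, against 51 of the 1749 in Pax5+/- against WT. This count does not bound the calls that follow sex either. With the closest pairs averaged, 420 of the 2292 passed, among them 175 of the 263 with a change over 2-fold and all of the 8 largest rises and 8 largest falls. Without replicates 1 and 3 of WT and Pax5+/-, with the same limit, 4757 passed. With the stromal covariate 1412 of the 2292 kept their call. The covariate did not overlap between these groups either, so the same limit holds.

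Interferon-response genes were higher here too: 15 of 22 rose, none fell and 7 did not pass, with a median of 0.486 (17 higher adjusted over the list alone, camera adjusted p = 6.58e-15, and adjusted p = 0.149 with an estimated correlation). Rsad2 rose by 1.56 (SE 0.0665), Ifih1, a sensor of viral RNA, by 1.32 (SE 0.108), Ifit1 by 1.38 (SE 0.126) and Bst2, the antiviral protein tetherin, by 0.83 (SE 0.101). Of 21 genes of immature and mature B cells 8 rose and Il2ra, whose call ended with the closest pairs averaged, fell by 0.62 (8 and 2 adjusted over the list alone, adjusted p = 0.00576, and adjusted p = 0.557 with an estimated correlation). The rises were led by Cd74, at 8.79 ± 0.0876 against 6.62 ± 0.0663 (log2 change 2.17, SE 0.128, adjusted p = 2.28e-07), H2-Aa at 0.69 and Ciita at 0.55. H2-Aa stayed low, at 5.82 against 5.13, where the lower quartile of an array lay at 5.57 to 5.64. In all, 6 of the list's members belong to the MHC class II pathway. With those 6 left out, a setting chosen after the result was seen, the list's median was -0.0025 and its call ended. It also ended without replicates 1 and 3 of WT and Pax5+/-. Both groups of genes rose on the arrays with Xist signal, and markers of monocytes, macrophages and plasmacytoid dendritic cells that moved beside them were Cd68, Spib and Bst2 upward and Ccr2, Irf8 and Ccr9 downward. The erythroid marker Aqp1 rose, and markers of T, NK, plasma and stromal cells moved both ways, among them Ccl5 and Alpl upward and Nkg7, Sdc1 and Cxcl12 downward.

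**Figure D4:**
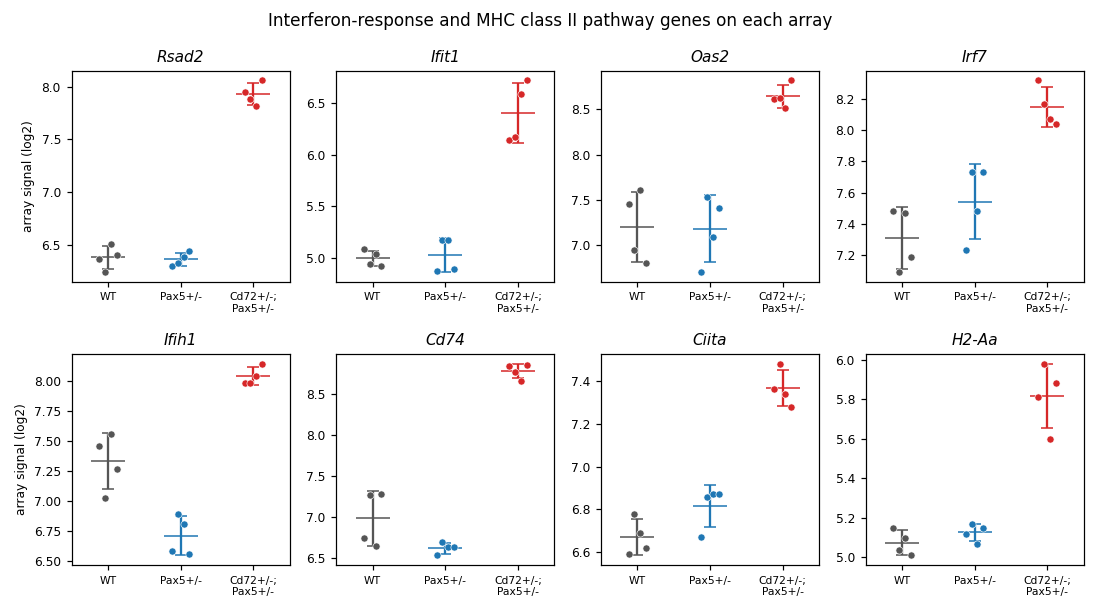
Log2 array signal (vertical axes, each with its own range) of the interferon-response genes Rsad2, Ifit1, Oas2, Irf7 and Ifih1 and of the MHC class II pathway genes Cd74, Ciita and H2-Aa in WT, Pax5+/- and Cd72+/-;Pax5+/-, with 1 point per array, a bar at the mean and error bars of 1 SD (n = 4). The Cd72+/-;Pax5+/- arrays lie above all other arrays in each panel, for example at 7.93 ± 0.103 for Rsad2 and 8.79 ± 0.0876 for Cd74.

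Of the lists that had fallen in Pax5+/- against WT, S phase and glycolysis were higher in Cd72+/-;Pax5+/- than in Pax5+/-, and G2 and M phase did not pass. Both tests use the same Pax5+/- arrays, so lists chosen as low there are favoured to go the opposite way. In Cd72+/-;Pax5+/- against WT neither S phase nor glycolysis passed (camera adjusted p = 0.778 and 0.689). Of 21 S-phase genes Rrm2, Uhrf1 and Cdt1 rose by 0.81, 0.31 and 0.39 (6 adjusted over the list alone, adjusted p = 0.000857, and adjusted p = 0.886 with an estimated correlation). Of 13 glycolysis genes Pfkp and Slc2a1 rose by 0.98 and 0.45 (2 adjusted over the list alone, adjusted p = 0.00576, and adjusted p = 0.902 with an estimated correlation). Of 18 Myc targets and ribosome-biogenesis genes, Polr1b rose by 0.95, none passed adjusted over the list alone, and the list passed as a whole with a median of 0.296 (adjusted p = 0.0106, and adjusted p = 0.902 with an estimated correlation). Of 51 small nucleolar RNAs 22 fell and Snora23 rose (31 and 1 adjusted over the list alone, adjusted p = 9.46e-10, and adjusted p = 0.663 with an estimated correlation), with Snord49b at -0.84 and Snord47 at -0.57. The 3 Y-linked genes fell and Xist rose (the same 3 and 1 adjusted over the list alone, adjusted p = 0.00109, and adjusted p = 0.557 with an estimated correlation). The calls of Uhrf1, Cdt1, Slc2a1 and Polr1b ended with the closest pairs averaged. With fry the calls of the S-phase, glycolysis and Myc lists ended (adjusted p = 0.051, 0.157 and 0.41). The call of the Myc list also ended without Pax5+/- replicate 2 (adjusted p = 0.0655) and without replicate 4 (adjusted p = 0.102).

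The remaining lists did not pass against Pax5+/-. Of 21 genes that Pax5 activates Bst1, Spib and Cd79a rose and Cd72, Ikzf3, Capn2, Cd55 and Irf8 fell, Ikzf3 by 1.51 (3 and 8 adjusted over the list alone, adjusted p = 0.0809). Bst1 rose by 2.09. Among genes that Pax5 represses Cd33, Itgal and Jchain fell (1 higher and 4 lower adjusted over the list alone, adjusted p = 0.729), and among genes of pro-B and pre-B identity Tcf3 and Runx1 rose and Cd24a, Cd93, Dntt and Myb fell (4 and 4 adjusted over the list alone, adjusted p = 0.965). Of 25 genes of B-cell receptor signalling 6 rose, among them Cd22 and Prkcb, and 6 fell, among them Cd72 and the phosphatase Ptpn6 (6 and 7 adjusted over the list alone, adjusted p = 0.729). Aurkb, Birc5, Bub1b and Foxm1 rose by 0.18 to 0.32 among 19 genes of G2 and M phase (adjusted p = 0.281). Ccnd3 and Cish rose among interleukin-7 genes, Bbc3, Pmaip1 and Zmat3 among p53 targets, Cox5a and Sdhc among oxidative phosphorylation genes, and Dnajb1 and Hspa1a among heat-shock genes. Ccl4 and Tnip1 rose and Nlrp3 fell by 1.79 among genes of NF-kB and inflammation, Slc2a1 rose and Insr and Slc2a6 fell among glucose-restriction genes, and Atf3 and Ier3 rose and Nr4a1 and Fosb fell among immediate-early genes (5 and 5 adjusted over the list alone, adjusted p = 0.967). Of 26 leukemia genes Bcor, Crebbp, Kdm5c and Tcf3 rose and Ikzf3 fell (5 and 3 adjusted over the list alone, adjusted p = 0.55), and of 41 chromosomal neighbours Ccdc107 rose and Car9 and Hint2 fell. Among markers of other cells, Aqp1, Lat, Ccl5, Alpl, Slamf7, Derl3 and Mzb1 rose and Cd5, Zap70, Nkg7, Sdc1, Jchain and Cxcl12 fell. No marker of granulocytes, stem cells, basophils or megakaryocytes passed, and the lists of other cell types had adjusted p from 0.281 to 0.985. Among the genes of these lists that the naming rule covers, Bst1, Cd72, Ikzf3, Capn2, Pmaip1, Ccl4, Nlrp3, Atf3, Nr4a1, Lat, Aqp1, Ccl5, Ccr2, Bst2, Alpl, Slamf7 and Sdc1 kept their calls with the closest pairs averaged, and the other calls ended. The median, the mean and the test differed in sign for genes that Pax5 represses and for immediate-early, monocyte, basophil and stem cell lists.

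Both mutant groups were compared with the same WT arrays. Among the clusters called in both comparisons 346 were higher and 242 lower in both, and 120 went opposite ways; independent lists of these sizes would share 41.3 and 27.4. Flt3, Ccl3 and Fundc2 were higher and Rnase12, Tjp1 and Cdkn2a lower in both. The shared WT arrays alone bring overlap. Unchanged groups in 100 simulations shared 0 calls, which says nothing on this, since such groups give almost no calls. The log2 changes correlated across genes with r = 0.378, and with r = 0.5 in the simulation; their covariance was 0.0227 against a simulated 0.00426, a difference of 0.0185. The simulation takes the WT arrays as independent, so it understates the covariance that they bring if the closest pairs repeat 1 sample. Genes are not independent replicates. With the WT arrays divided between the comparisons, the number of shared calls was 317, 319, 322 and 331 when each side held 1 array of each closest pair. Independent lists would share 12.6 to 14 higher and 6.38 to 6.9 lower there, and 41 to 53 clusters went opposite ways. With WT replicates 1 and 3 for Pax5+/- and 2 and 4 for Cd72+/-;Pax5+/-, 357 were higher and 236 lower in both, against 67.5 and 53.7 for independent lists. Here r was 0.285, the covariance was 0.0183 and 275 went opposite ways. With these pairs exchanged, 329 were higher and 244 lower in both, against 193 and 186 for independent lists. There r was -0.0787, the covariance was -0.00706 and 1425 clusters went opposite ways. The overlap thus depends on which WT pair serves which comparison, and for the clusters as a whole a shared change beyond the shared WT arrays is not established. Single genes can differ from every WT array in both mutants. Rnase12 read 8.85 to 9.08 on the WT arrays and 5.09 to 5.31 on the arrays of both mutant groups.

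Of the 1001 clusters higher in Pax5+/- than in WT, 529 were called lower in Cd72+/-;Pax5+/- than in Pax5+/-, Pgr, Il18r1 and Nlrp3 among them, 42 were higher still, and 430 did not pass it. Of the 748 lower in Pax5+/-, 317 were called higher in Cd72+/-;Pax5+/- than in Pax5+/-, among them Bst1, Alpl, Cd84 and Rrm2, 27 were lower still, and 404 did not pass. Both tests use the same Pax5+/- arrays, so clusters chosen as high or low there are favoured to go the opposite way in the second test, and how many would do so without a change was not computed. Cd72+/-;Pax5+/- differed in the same direction from both other groups in 846 clusters, 417 higher, such as Slamf6, Car13 and Rsad2, and 429 lower, such as Ccr2, Slc30a4 and Ikzf3. In all, 271 clusters passed in the 3 comparisons. For 657 of the 846, Pax5+/- and WT did not differ by the test.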

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

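The tests of neighbouring genes, of the surroundings of Cd72, of sex and of other cell types were chosen after the results they address were seen, and the counts over other splits of the arrays were planned.

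In a group of 4 arrays, an array was singled out when its gap to the nearest other array took most of the group's range (Dixon's test). Of 1008 groups from 304 genes and from the gene lists, 38 met this, against 50.4 that a rate of 1 in 20 gives by chance, so the number itself needs no explanation. Only Cox4i1 and Ifi206 were far from the others in size. Cox4i1, a subunit of cytochrome oxidase, read 10.27 in Pax5+/- replicate 1 against 9.71 to 9.8 in the others. Ifi206, of the interferon-inducible Ifi200 family, read 6.8 in Cd72+/-;Pax5+/- replicate 4 against 6.19 to 6.25.

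The other single arrays lay closer to their groups. In WT they were replicate 1 for Crebbp (11.22), Cd68 (7.58), Slamf9 (6.63) and Pcdhb14 (5.2), replicate 2 for Cdh5 (6.41), replicate 3 for Snord47 (12.35) and Cd44 (8.08), and replicate 4 for Pcdhb3 (4.93) and the mean of megakaryocyte markers (6.024). In Pax5+/- they were replicate 1 for Ciita (6.67), Derl3 (7.38), Klf6 (8.87), Cxcl2 (5.38) and the means of the interferon list (6.808), of granulocyte markers (6.059) and of T-cell markers (6.405), replicate 2 for Bst2 (7.66) and Snord35b (8.95), and replicate 3 for Ccnd3 (9.88), Snord49b (13.18), Clta (9.41) and H2-Ob (9.6). In Cd72+/-;Pax5+/- they were replicate 1 for Alpl (9.06), Dusp1 (9.21), Pcdhb13 (5.45) and Ywhaz (13.09), replicate 2 for Gadd45a (8), and replicate 3 for Flt3 (10.29) and Insr (8.53). Replicate 4 of that group was singled out for Cd3e (6.85), Mcpt8 (5.04), Usp18 (6.37), Sdhb (10.73), H2-Oa (7.08) and the means of the glucose-restriction list (8.492) and of the chromosomal neighbours of Cd72 and Pax5 (8.232).

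Clusters without a gene symbol were left out of the report's counts and entered only an alternative that tested all clusters. Of these 5534 clusters, 316 passed in Pax5+/- against WT (202 higher, 114 lower), 209 in Cd72+/-;Pax5+/- against WT (117 higher, 92 lower) and 386 in Cd72+/-;Pax5+/- against Pax5+/- (172 higher, 214 lower), when all clusters were tested together, so they also differed between the groups. What these clusters measure was not tested.

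The counts of called genes were compared with those from the 35 splits of the 8 arrays of a comparison into 4 and 4, the real split included. For clusters called after adjustment, 1 split gave a count as large in each comparison, the real one. The real counts were 1749, 1821 and 2292, and the highest of the other splits gave 1434, 0 and 0. The split with 1434 set replicates 1 and 3 of Pax5+/- and of WT against replicates 2 and 4, so it points to a structure of the samples besides the genotype. For the study's threshold 1 split, the real one, reached 224, 214 and 280, against 46, 31 and 26 in the highest of the others. Chance can be excluded for these counts only if the arrays are independent samples. If the closest pairs repeat 1 sample, each group has 2 units, too few splits exist for a share under 0.05, and these counts of splits do not exclude chance. For the number of gene lists chance could not be excluded: 22, 6 and 10 of the 35 splits gave as many lists as the real 4, 7 and 7, and the highest of the others gave 11, 9 and 10.

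The first pattern weighed was the rise of interferon-response and MHC class II genes in Cd72+/-;Pax5+/- against Pax5+/-. Sex of the animals cannot be told apart from the genotype: 4 Cd72+/-;Pax5+/- arrays and 0 of the others had Xist signal. Mature B cells, macrophages or plasmacytoid dendritic cells left in the sort are a candidate source of MHC class II transcripts. Of 39 markers of these cells outside the MHC and interferon genes, 4 were called higher (Cd68, Spib, Ccr7 and Cd22) and 4 lower (Ccr2, Irf8, Ccr9 and Il2ra), with a median log2 change of 0.015 (95% bootstrap bounds -0.0325 to 0.0725), against 0.582 for the 6 MHC members. Because the markers went both ways and pro-B cells express some of them, this explanation also stays open for the MHC genes, and so does an effect of the lost copy of Cd72, which the design names.

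The second pattern was that genes called with a change over 2-fold lie next to each other. Of the called genes, 21, 18 and 25 had an adjacent called gene in the 3 comparisons, against 4.17, 2.95 and 5.92 with calls shuffled among genes of like signal, which linked loci of different genetic background between the groups may explain. With neighbours of the same symbol stem not counted, 12, 14 and 11 remained, which still includes relatives with other symbols, such as Aim2 beside Ifi206, and the Y-linked Kdm5d, Eif2s3y and Uty, which follow the sex of the arrays. With the families described under the other observations and neighbours on chromosomes X and Y also not counted, 10, 7 and 2 remained, against 3.85, 2.7 and 5.43 expected and upper bounds of 10, 8 and 12 from the shuffles, so no count exceeded its bound. Gene families or near-identical copies with shared probes, together with sex, therefore stay open beside genetic background and regulation of linked genes by the genotype, and these families were themselves chosen from the called genes.

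The third pattern was where the calls lie relative to Cd72, since a passenger segment carried along with the Cd72 allele could change its neighbours. In Cd72+/-;Pax5+/- against Pax5+/-, 7 of the 100 tested genes nearest Cd72 were called, or 7%, against 10.1% of all genes and a 95th percentile of 17% over 17845 windows elsewhere. This argues against passenger genes linked to the Cd72 allele as the source of many calls. The window says nothing about segments elsewhere.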

How the results depend on the processing

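The settings with averaged or blocked pairs, the stromal covariate, the omission of replicates 1 and 3 of WT and Pax5+/-, the omission of genes on chromosomes X and Y, and the lists without certain members were chosen after seeing the data, and the others were planned; the cause of a change was not tested unless it is named. Comparisons are given in the order Pax5+/- against WT, Cd72+/-;Pax5+/- against WT, Cd72+/-;Pax5+/- against Pax5+/-. No paired analysis was possible because the sample numbers run from 1 to 12 and no number is shared between groups.

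Called clusters numbered 282, 290 and 420 with the closest pairs averaged, which leaves 2 values per group, and 1133, 1031 and 1398 with the pairs as a random block. The stromal covariate gave 2748 in the first comparison, array weights 2787 in the second, and omission of the 4 arrays, which leaves 1 closest pair with its small spread in WT and in Pax5+/-, 5359, 4427 and 4757, with 432 clusters past the study's threshold in the first. Under the other settings the counts stayed within 1.5 times those reported. Without 1 array, called clusters ranged from 1338 to 1959, 1257 to 1774 and 1667 to 2331, and clusters past the study's threshold from 202 to 253, 209 to 233 and 273 to 289.

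The number of lists past camera fell to 0, 0 and 0 with the estimated correlation and rose to 10 in the first comparison without the 4 arrays. Without 1 array it ranged from 2 (without Pax5+/- replicate 4) to 6, 5 to 8, and 6 to 10. The list tests were repeated with the estimated correlation, fry, quantile normalization, the filter on dim clusters, averaged pairs, omission of the 4 arrays and omission of each array in turn. Certain members were also left out of 2 lists. Of 18 calls of lists, 10 held in each of these settings other than the estimated correlation. The lists were not tested with the random block, the stromal covariate or the remaining settings.

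With the closest pairs averaged, the log2 changes were 1.288 for Cd72 (adjusted p = 0.173; range over 20 alternatives 1.82e-07 to 0.173) and -0.5975 for Pax5 (0.289; 1.87e-05 to 0.289) in the first comparison, and -1.388 for Cd72 in the second (0.137; 1.16e-05 to 0.137). Averaging pairs of equal size leaves these sizes as they were by construction. The calls ended with 2 values per group, which keep the spread between the pairs. With the stromal covariate Cd72 was at -0.958 in the second comparison (0.0798). Pax5 passed in the second comparison with the covariate (-0.841, adjusted p = 0.000687), without the 4 arrays (-0.485, 0.000322) and with only the 2 groups compared (-0.3625, 0.0202), within a range of 0.000322 to 0.592. In the third the covariate reversed it to -0.01803 (0.935; range 0.123 to 0.935). Without 1 array, Cd72 ranged from 1.131 to 1.451, -1.544 to -1.224 and -2.728 to -2.618, and Pax5 from -0.6775 to -0.4908, -0.4183 to -0.3117 and 0.1283 to 0.315; no call of either gene changed.

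Of 229 calls of named genes, 98 held with averaged pairs, 186 with the random block, 178 with the covariate, 208 with only the compared groups, 222 without the 4 arrays, 218 after quantile normalization, 224 after the median shift, 218 with the trend and robust prior, and 225 with array weights. The covariate reversed 4 in the second comparison: Cdt1 (-0.06007), Rgp1 (-0.0487), Cxcl12 (0.09664) and Sparc (0.6084). Cxcl12 and Sparc belong to the list whose mean is the covariate, and so does Alpl. The covariate itself differs between the groups, so results with it are no check on stromal content.

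Changes shared by both mutants fell from 346 higher and 242 lower to totals of 317, 319, 322 and 331 with WT arrays divided across the closest pairs, where each comparison has 2 WT arrays. Genes near the background of the arrays limit what small changes can be seen.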

Other observations

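The families described here, and the tests behind them, were chosen after their values were seen. Slam-family receptors regulate contacts between lymphocytes. Of 9 members, 1 rose and 3 fell in Pax5+/- against WT, 4 rose in Cd72+/-;Pax5+/- against WT, and 5 rose and 1 fell in Cd72+/-;Pax5+/- against Pax5+/-; the others did not pass. Cd48 fell by 1.75 in Pax5+/- and rose by 2.64 from there to Cd72+/-;Pax5+/-, and Cd84 fell by 2.62 and rose by 2.17, while Slamf6 and Slamf7 passed only in the comparisons with Cd72+/-;Pax5+/-. Cytosolic DNA sensors and their relatives of the Ifi200 family, 10 genes, did not move as a block: Aim2 fell by 2.44 in Cd72+/-;Pax5+/- against WT and Ifi202b fell by 2.71, while Ifi208 rose by 2.12 and Ifi206 by 1.51. Beta protocadherins, cell-adhesion genes known from neurons, rose in Pax5+/- in 5 of 22 members, among them Pcdhb17 by 1.61 and Pcdhb16 by 1.48. They fell in 4 and rose in 0 in Cd72+/-;Pax5+/- against WT. In Cd72+/-;Pax5+/- against Pax5+/- they fell in 7, and Pcdhb16 changed by -3.01. All of these calls lie in the stretch from Pcdhb16 to Pcdhb22, and none of Pcdhb1 to Pcdhb15 passed. Cd48, Cd84, Slamf6 and Slamf7 also lie close together, as do Aim2, Ifi206, Ifi208 and Ifi202b. Such neighbouring calls are weighed above as the second pattern.

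MHC class II genes were not uniform either. In Cd72+/-;Pax5+/- against Pax5+/-, 6 of 9 rose, among them Cd74, H2-Aa and H2-DMa (0.62), while H2-Oa and H2-Ob, subunits of an inhibitor of peptide loading, fell by 0.69 and 1.02. Of 7 commonly used reference genes only Ywhaz passed, at -0.30 in Pax5+/- against WT and 0.23 in Cd72+/-;Pax5+/- against Pax5+/-. Of 4 genes known to escape X inactivation, Kdm5c and Eif2s3x rose by 0.49 and 0.44 in the latter comparison and Ddx3x and Kdm6a fell by 0.23 and 0.27. Among the 71 calls in these families, quantile normalization and a common median changed the sign of 0 and ended 7 and 3.

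Single genes divided the WT arrays along the closest pairs, and these too were chosen after their values were seen. Lta, a cytokine of lymphoid organs, read 7.1, 10.14, 7.09 and 10.15 in WT replicates 1 to 4, Dntt 11.93, 9.76, 11.92 and 9.82, Bcl2, which protects lymphocytes from death, 9.54, 11.55, 9.62 and 11.48, and Myc 10.1, 11.86, 10.12 and 11.83. The Pax5+/- arrays read 7.18, 7.16, 6.97 and 7.26 for Lta, and for Sparc, a matrix protein of stromal cells, 10.79, 8.7, 10.85 and 8.59. Clusters with an SD over 0.5 numbered 340 in WT, 161 in Pax5+/- and 9 in Cd72+/-;Pax5+/-. The labels give no batch or date, and no explanation of these values was tested.

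Genes of the interferon list also mark other processes, so its call was repeated without Cxcl10 and Bst2, which NF-kB and plasmacytoid dendritic cells share. The median stayed at 0.454 against WT (adjusted p = 5.36e-10; range over 15 alternatives 2.7e-13 to 0.259) and was 0.475 against Pax5+/- (5.79e-13; range 1.53e-15 to 0.149).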
